A study of Mus musculus with 3 samples.

How the data were processed

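Total RNA from 3 cultures of the mouse cell line 32Dc was measured on 1-colour oligonucleotide arrays with 45101 probe sets, 1 array for each culture. Per the labels' protocols, RNA was isolated with Trizol and cleaned on spin columns, cDNA was primed with a T7-oligo(dT) primer from 3 µg of RNA, and biotin-labelled cRNA was made by in vitro transcription. The deposited values are intensities on a linear scale, 1 per probe set and array, and were made with MAS5, per the submitters' processing notes. MAS5 combines the matched and mismatched probes of a probe set into a single signal and multiplies each array by a factor. Its version and settings, and the scanner files, were not given in the sources used here. The mean of each deposited column without its top and bottom 2% was 500.0, so the arrays already shared 1 scale. Priming from the 3' end makes the signals depend on where a probe set lies in the transcript, and signals near background vary more than bright ones.

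Each array was multiplied to 1 mean of this trimmed kind, which moved nothing here. A floor was set at the 50th percentile of the probe sets, a scaled signal of 75.5, and lower signals were set to it. The 27 probe sets for bacterial transcripts that no sample contains had highest signals of 54.6, 36.7 and 27.2 on the arrays of 32Dc, MLL-AF4 and MLL-AF4 plus Flt3 TKD, all under the floor. A gene was represented by its probe set of the highest mean signal among those with 1 gene symbol. The log2 ratio of the floored signals was taken for each pair of arrays. A gene at the floor on both arrays got no ratio, and a gene at the floor on 1 of them got a bound, written as at least so many fold. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 matched a RefSeq gene of the assembly GRCm38.p6 by gene identifier, and 0 symbols changed through that match. This left 18194 genes, of which 9012 had more than 1 probe set.

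With 1 array per group there was no replicate, no test and no p-value. The number of arrays limits the precision of every value. As a measure of spread, the robust SD of the log2 ratio between MLL-AF4 and 32Dc was 0.24 over the 7941 genes whose brighter signal exceeded 4 times the floor, and 0.40 over the 2781 dimmer genes. For MLL-AF4 plus Flt3 TKD against 32Dc these SDs were 0.44 and 0.46. They hold real differences as well as noise.

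The choices of scaling, floor, probe set, threshold, comparisons and gene lists were made before the data were examined. A gene counted as different at 2-fold. For each comparison the text names the 8 genes with the largest log2 ratio in each direction among those above the floor on both arrays, and the 4 largest bounds in each direction. Clone and model names, and genes with another probe set 2-fold the other way, were left out of these. It also names up to 4 members of a gene list with the largest absolute log2 ratio, and always Flt3, Kmt2a, Aff1, Hoxa9, Meis1, S100a6, Il3ra and Csf2rb. Further list members, and genes already named for another comparison, were added after their values were seen, to show the spread of a list or a gene's signal across the arrays. There were 31 gene lists with 592 distinct genes, of which 534 had a named probe set. They covered MLL targets, blood lineages, signalling responses, metabolism, control genes and markers of other cells. The median log2 ratio of a list, with bounds at their value, was set among 10000 random lists of the same size, drawn from 20 bins of like signal. The range of the random lists runs from their 2.5th to their 97.5th percentile. It describes these arrays and tests no condition. A list with fewer than 3 measured members got no median.

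After the data were seen, the genes were put in RefSeq order and the median log2 ratio of 41 neighbouring genes was run along it. A run of neighbours was called where windows exceeded the largest window in 1000 shuffles of the order, and windows of a run could lie up to a window apart. Neighbouring genes are not independent, so the shuffles are a yardstick and not a test.

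The steps were checked on simulated arrays with the mean signals of these arrays and the spread between MLL-AF4 and 32Dc as noise. For that comparison, with 10874 genes in the step, 22 of 40 bright genes made 2-fold different were called, as were 40 of 40 at 3-fold. Of 10556 unchanged genes 135, or 1.28%, reached 2-fold. A list of 20 genes raised together lay at the 100th percentile of random lists, and an unchanged list lay at 95.2. In the step with 10856 genes, a run of 100 raised neighbours was found as 1 run with 96 of its genes and 2 others. With no run simulated for MLL-AF4 plus Flt3 TKD against 32Dc, 0 runs were found. The noise was drawn for each gene on its own, so this outcome was nearly fixed beforehand. It does not show how often runs arise where neighbouring genes vary together.

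The alternative settings fixed beforehand were the deposited scale, quantile normalization, a common median of the probe sets above the floor, floors at the 25th and 75th percentiles, the median over all probe sets of a gene, leaving out probe sets of the less specific types, and a threshold of 3-fold. Scaling to the 18 hybridization controls, bacterial and phage RNAs of known amount added before hybridization, was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.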

Results

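Gene expression was measured in 3 cultures of 32Dc, a mouse myeloid progenitor line of the 32D family, which grows in interleukin-3. The first culture was 32Dc itself. The second expressed MLL-AF4, the product of a fusion of the genes MLL (Kmt2a) and AF4 (Aff1) that occurs in acute leukaemia. The third expressed MLL-AF4 plus Flt3 TKD, a form of the receptor tyrosine kinase Flt3 that the labels name by its tyrosine kinase domain. Each culture was represented by 1 array, so no difference given here has a replicate check.

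The share of probe sets above the floor was 50.5% for 32Dc, 49.5% for MLL-AF4 and 49.9% for MLL-AF4 plus Flt3 TKD. The ratio of the 3' to the 5' signal of the Gapdh control, a sign of RNA quality, was 0.827, 0.815 and 0.789 in the same order. That of the actin control was 1.74, 1.58 and 1.57, and that of the transferrin receptor control was higher, at 3.66, 3.28 and 3.65. The 18 hybridization controls had geometric mean signals of 2561, 2409 and 2114. They were thus lower on the array of MLL-AF4 plus Flt3 TKD, by a mean log2 ratio of −0.28 (SD 0.13 over the controls) against 32Dc, whereas the median of all genes was 0.02. Over 9394 genes above the floor on all arrays, log2 signals of 32Dc and MLL-AF4 correlated across genes with r = 0.981, and those of 32Dc and MLL-AF4 plus Flt3 TKD with r = 0.938. Genes are not independent replicates.

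The genes of the introduced proteins had similar or low signals throughout. Flt3 was near the floor, with signals of 63.6 in 32Dc, 84.7 with MLL-AF4 and 41.8 with MLL-AF4 plus Flt3 TKD. Kmt2a gave 1185, 1168 and 1323, and Aff1 gave 2537, 2279 and 2005. The probe sets are those of the mouse transcripts, and the species and extent of the introduced cDNAs were not given in the sources used here, so these values do not check the labels. Hoxa9 and Meis1, homeobox genes that MLL fusions are known to activate, had low signals of 70.3, 122 and 97.7 for Hoxa9 and 111, 126 and 147 for Meis1.

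The first comparison asks which transcripts differed in 32Dc cells that expressed MLL-AF4. Genes of neutrophil granules and of the interferon response were higher as lists with MLL-AF4. Elane, which encodes neutrophil elastase, had a signal of 146 in 32Dc and 3206 with MLL-AF4, 22.0-fold higher. Usp18, an interferon-induced protease that removes ISG15, was 15.96-fold higher, at 119 and 1895. Fcer1a, the alpha chain of the high-affinity IgE receptor of mast cells and basophils, had a signal of 6390 in 32Dc and 4.74 with MLL-AF4, under the floor and at least 84.6-fold lower.

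Of 10722 genes with a ratio, 150 were at least 2-fold higher and 114 at least 2-fold lower with MLL-AF4, of which 30 and 44 were bounds. When arrays were scaled to the hybridization controls, these counts were 176 and 84. The main counts were 1.40% and 1.06% of the genes. In the simulation with the spread of this pair as noise, 1.28% of unchanged genes reached 2-fold either way. Noise may therefore make up part of the counts. Among the genes higher on the array, Chil3 (a chitinase-like protein of myeloid cells) differed 9.60-fold, Ceacam10 7.48-fold, Dnah8 7.21-fold, Rsad2 6.44-fold, Oas2 5.90-fold and Cst7 5.39-fold. Ifit1 was at least 5.05-fold higher, Syngr1 at least 5.04-fold, Pdgfrb at least 4.81-fold and Pygl at least 4.57-fold. Among the lower genes were Padi2 (7.38-fold), Tcl1b3 (6.13-fold), Zap70 (6.02-fold), Aox4 (5.47-fold), P2rx7 (4.17-fold), Ift43 (3.90-fold), Mapk8ip2 (3.83-fold) and Mamdc2 (3.27-fold). Zap70 and Aox4 lie in a stretch of 163 neighbouring genes, from Prim2 to Tuba4a, whose median log2 ratio was −0.36, far smaller in size than theirs. The Zap70 ratio rests on 1 probe set, as its others were under the floor on all arrays. The median over all probe sets of Mapk8ip2 was only −0.38 on the log2 scale. Gtsf1 was at least 43.7-fold lower, Btg1, an antiproliferative gene, at least 36.0-fold, and Oosp1 at least 13.5-fold. Where other probe sets of a gene were measured, at least 1 went the same way for 39 of 50 higher and 30 of 34 lower genes. At least 1 reached 2-fold the same way for only 22 of the 50 and 12 of the 34.

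Of 25 measured interferon-response genes, 14 were at least 2-fold higher and 0 were lower, with a median log2 ratio of 1.03 against a range of −0.17 to 0.14 for random lists. Besides Usp18, Rsad2 and Oas2, this list held Xaf1 (log2 ratio 2.34, but 1.08 as the median over its probe sets, of which the other did not go the same way), Oas3 (2.13), Irf7 (1.79) and Bst2 (1.47). The 10 measured genes of MHC class I and its antigen processing, which interferon also induces, held 0 members at 2-fold and had a median of −0.07, within a range of −0.17 to 0.17 and of the other sign when scaled to the hybridization controls. Of 12 genes on the primary granule list, 5 were at least 2-fold higher and 0 lower (median 0.91, range −0.15 to 0.13), among them Mpo, myeloperoxidase, at 4644 and 14106. Not all genes of that list encode granule proteins, as Gfi1 is a transcription factor. Of 18 secondary and tertiary granule genes, 6 were higher and 0 lower (median 0.63, range −0.17 to 0.14), with Cd177 at 2.39, Camp at 2.37 and Ltf, lactoferrin, at 1.92. Monocyte and macrophage markers had 3 of 19 members higher, Lyz2, Cd14 and Lyz1, and a median of 0.33 (range −0.18 to 0.15). The Lyz1 ratio rests on a less specific type of probe set, which may also detect related transcripts. Another Lyz1 probe set was under the floor on all arrays (16.2, 28.1 and 17.5), so Lyz1 may not be a separate signal.

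S100a6, a calcium-binding protein, had a signal of 499 in 32Dc and 1120 with MLL-AF4, a log2 ratio of 1.17. It was the only one of 8 measured S100 family members at 2-fold, and their median was 0.59 (range −0.17 to 0.17). S100a8, S100a9 and S100a5 followed with 0.76, 0.69 and 0.64. S100a9 gave the highest signal of the MLL-AF4 array, where a saturated signal would make its ratio too small. All 8 members lie inside a stretch of 94 neighbouring genes, from Syt11 to Mcl1 in the RefSeq order of GRCm38.p6, whose median log2 ratio was 0.40. Cholesterol synthesis genes had 0 of 17 members at 2-fold and a median of 0.44 (range −0.13 to 0.13), led by Pmvk (0.90), Idi1 (0.80) and Fdps (0.79), of which Pmvk and Fdps lie in the same stretch. Cell cycle genes had 0 of 25 at 2-fold and a median of 0.16 (range −0.10 to 0.10).

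Of the receptor subunits for interleukin-3 and related cytokines, Csf2rb2 was at least 2-fold lower with MLL-AF4, at 6844 and 3283 (log2 ratio −1.06). Il3ra gave 368 and 196 (−0.91) and Csf2rb gave 11635 and 7644 (−0.61), both under 2-fold, and the 19 measured cytokine receptors had a median of −0.00. Of 20 myeloid transcription factors, Cebpd was higher (1.07) and Cebpa, a regulator of granulocyte differentiation, was lower (−1.50). Mast cell and basophil markers had 1 of 15 members higher, Ms4a2 (1.05), and 2 lower, Fcer1a and Gzmb (−1.45). The known targets of MLL fusions had a median of −0.00 over 21 measured members, of which Prom1 was at 2-fold (2.36). Of the HoxA cluster only Hoxa5 and Hoxa9 were above the floor on either array, and of the 9 HoxB genes with a probe set, 0 were. Single members at 2-fold in other lists were Itgb3 (1.98) and Gp1bb (bound −1.23) among megakaryocyte markers, Zap70 (−2.59) among T and NK cell markers, Pdgfrb (bound 2.27) among stromal markers, Ccl5 (1.66) among inflammatory genes, Atf3 (bound −1.84) in the stress response, Il10ra (bound 1.10) among receptors and Bcl6 (−1.02) among STAT5 targets. In all, 7 of 29 list medians lay above the range of random lists and 0 below it.

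**Figure D1:**
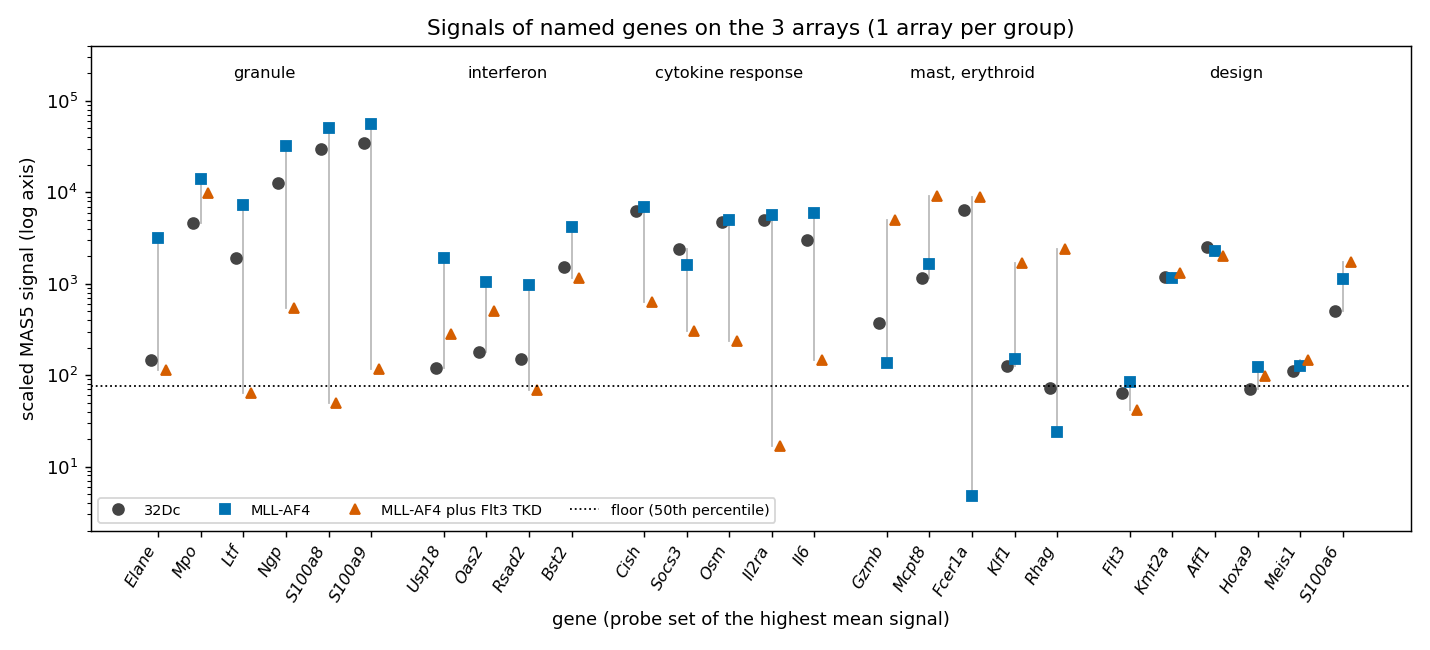
Scaled MAS5 signals (log axis) of named genes on the arrays of 32Dc (circles), MLL-AF4 (squares) and MLL-AF4 plus Flt3 TKD (triangles), 1 array each, with thin lines spanning the 3 values and the floor of 75.5 dotted. S100a9 stands at 34371, 55588 and 117, and Fcer1a at 6390, 4.74 and 8916.

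The second comparison asks how cells with both proteins differed from 32Dc. Secondary and tertiary granule, inflammatory and cytokine-response genes were lower as lists with MLL-AF4 plus Flt3 TKD. Some genes of the mast cell, erythroid and platelet lineages were higher, but the mast cell and platelet lists also held lower members. S100a9, a subunit of calprotectin, had a signal of 34371 in 32Dc and 117 with both proteins, 295-fold lower, and its partner S100a8 gave 29732 and 49.2, at least 394-fold lower. Selp, the adhesion molecule P-selectin, was 21.2-fold higher (84.6 and 1792), and Klf1, a transcription factor of red cell precursors, was 13.4-fold higher (126 and 1685). S100a6 was also higher, at 499 and 1731, 3.47-fold.

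Of 10801 genes with a ratio, 334 were at least 2-fold higher and 540 at least 2-fold lower, of which 62 and 117 were bounds. Scaled to the hybridization controls, which put the median of all genes at 0.28 in place of 0.02, the counts were 780 and 347. The list medians outside the range of random lists kept their sign under that scaling, whereas those of the primary granule, stem and progenitor, stromal, MHC class II, BCL2 family, ribosomal protein and housekeeping lists, all within it, did not. Further large ratios were found for Tgfbr3 (18.2-fold higher), Gzmb, the protease granzyme B (13.4-fold), Pdzk1ip1 (11.2-fold), Gp9 (9.11-fold), Hdc, the enzyme that makes histamine (8.93-fold), and Fgf3 (8.50-fold). Rhag, a red cell membrane protein, was at least 31.9-fold higher, Igsf6 at least 8.57-fold, Prss28 at least 8.39-fold and Gem at least 7.21-fold. Among the lower genes were Ifitm6 (92.5-fold), Phlda1 (33.9-fold), Ngp (23.7-fold), Ccl6 (23.1-fold), Slc39a8 (21.6-fold), Il6 (20.7-fold) and Osm (20.5-fold). Il2ra was at least 66.9-fold lower, Stfa2l1 at least 55.1-fold and the chemokine Cxcl2 at least 45.0-fold. Another probe set went the same way for 141 of 149 higher and 225 of 234 lower genes, and reached 2-fold for 80 and 144.

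Of 15 secondary and tertiary granule genes, 9 were at least 2-fold lower and 0 higher (median −1.32, range −0.28 to 0.27). The primary granule list, which holds more than granule proteins, went both ways, with 3 higher and 3 lower of 12 and a median of −0.08. Igsf6 (bound 3.10), Mpo (1.08) and Cst7 (1.01) were higher, and Gfi1 (bound −3.99), Serpinb1a (−2.29) and Hp (−1.26) lower. Monocyte and macrophage markers had 8 of 18 members lower and 0 higher (median −0.98, range −0.24 to 0.28), led by Ccl3 (−3.84) and Adgre1, the F4/80 antigen (−3.20).

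Genes that respond to cytokine and growth factor signals were lower as groups. Of 19 STAT5 targets, 5 were at least 2-fold lower and 1, Ccnd1 (bound 1.19), higher, with a median of −0.71 (range −0.22 to 0.24). Il2ra, Osm (−4.36), Cish (−3.33) and Socs3 (−2.97), the latter pair being feedback inhibitors of cytokine receptors, led the lower members, whereas Pim2 (0.59) and Id1 (0.10) were not lower. Of 21 ERK feedback and immediate early genes, 12 were lower and 0 higher (median −1.31, range −0.22 to 0.27), with Phlda1 at −5.08, Cd69 at −4.16, and, as bounds, Dusp5 at −3.67 and Egr2 at −2.88. That median was −0.57 with the floor at the 75th percentile. NF-kB and inflammatory genes had 7 of 21 members lower and 0 higher (median −0.82, range −0.22 to 0.23). Glycolysis and hypoxia genes had 10 of 21 lower and 0 higher (median −0.93, range −0.22 to 0.16), among them Bnip3 (−2.41), Ankrd37 (−2.15), Ero1a (−2.07) and the glucose transporter Slc2a1 (−1.90). The amino acid and ER stress response had 7 of 21 lower and 0 higher (median −0.68, range −0.21 to 0.17), led by Trib3 (−2.41).

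Of 8 measured erythroid markers, 4 were at least 2-fold higher and 0 lower (median 0.78, range −0.40 to 0.41): Rhag (bound 4.998), Klf1 (3.74), Epb42 (1.55) and Gata1 (1.11). Mast cell and basophil markers split, with 5 of 15 higher and 3 lower and a median of 0.48 (range −0.27 to 0.27). Gzmb (3.74), Hdc (3.16) and Mcpt8 (3.01) stood against Il6 (−4.37). Megakaryocyte and platelet markers had 2 of 10 higher, Gp9 (3.19) and Gp5 (1.98), and 2 lower, Rab27b (−2.38) and F2r (−1.14). The median of that list was −0.36 (range −0.40 to 0.38). Among 21 myeloid transcription factors, 4 were higher and 5 lower, including the erythroid and megakaryocyte factors Zfpm1 (2.38) and Gfi1b (1.58) against Gfi1. Among stem and progenitor markers 3 of 13 were higher, including Lmo2 (2.28) and Angpt1 (1.94), and 5 lower, including Mycn (−1.52) and Cd48 (−1.32). Cell cycle genes had 2 of 25 members at 2-fold, both higher, and a median of 0.61 (range −0.19 to 0.17), with Ccnb2 at 1.08 and Mki67 at 0.94.

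The receptor subunits Il3ra (368 and 460) and Csf2rb (11635 and 11628) were near their 32Dc level, and Il4ra (−3.73) and Csf3r (bound −2.37) were lower. MLL fusion targets had 3 of 21 members higher, Lmo2, Bmi1 (1.15) and Cdkn1b (1.12), and 2 lower, with a median of 0.17 (range −0.23 to 0.23). The median over all probe sets of Cdkn1b was 0.48. Hoxa5 was lower (244 and 107). The interferon-response list had 4 of 23 members higher and 1 lower and a median of 0.15 (range −0.20 to 0.26). Of 5 measured B lymphoid markers 1, Bank1 (121 and 611), was at least 2-fold higher, and their median of 0.81 lay above the range of random lists (−0.61 to 0.60), but was −0.14 with the floor at the 25th percentile. Of 4 measured stromal markers 1, Col5a1 (55.4 and 439), was higher. Of 5 T and NK cell markers 0 were higher and 2 lower, Thy1 (bound −1.47) and Il2rb (bound −1.38), with a median of −0.61 (range −0.65 to 0.66). In all, 4 of 30 list medians lay above the range of random lists and 7 below it.

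**Figure D2:**
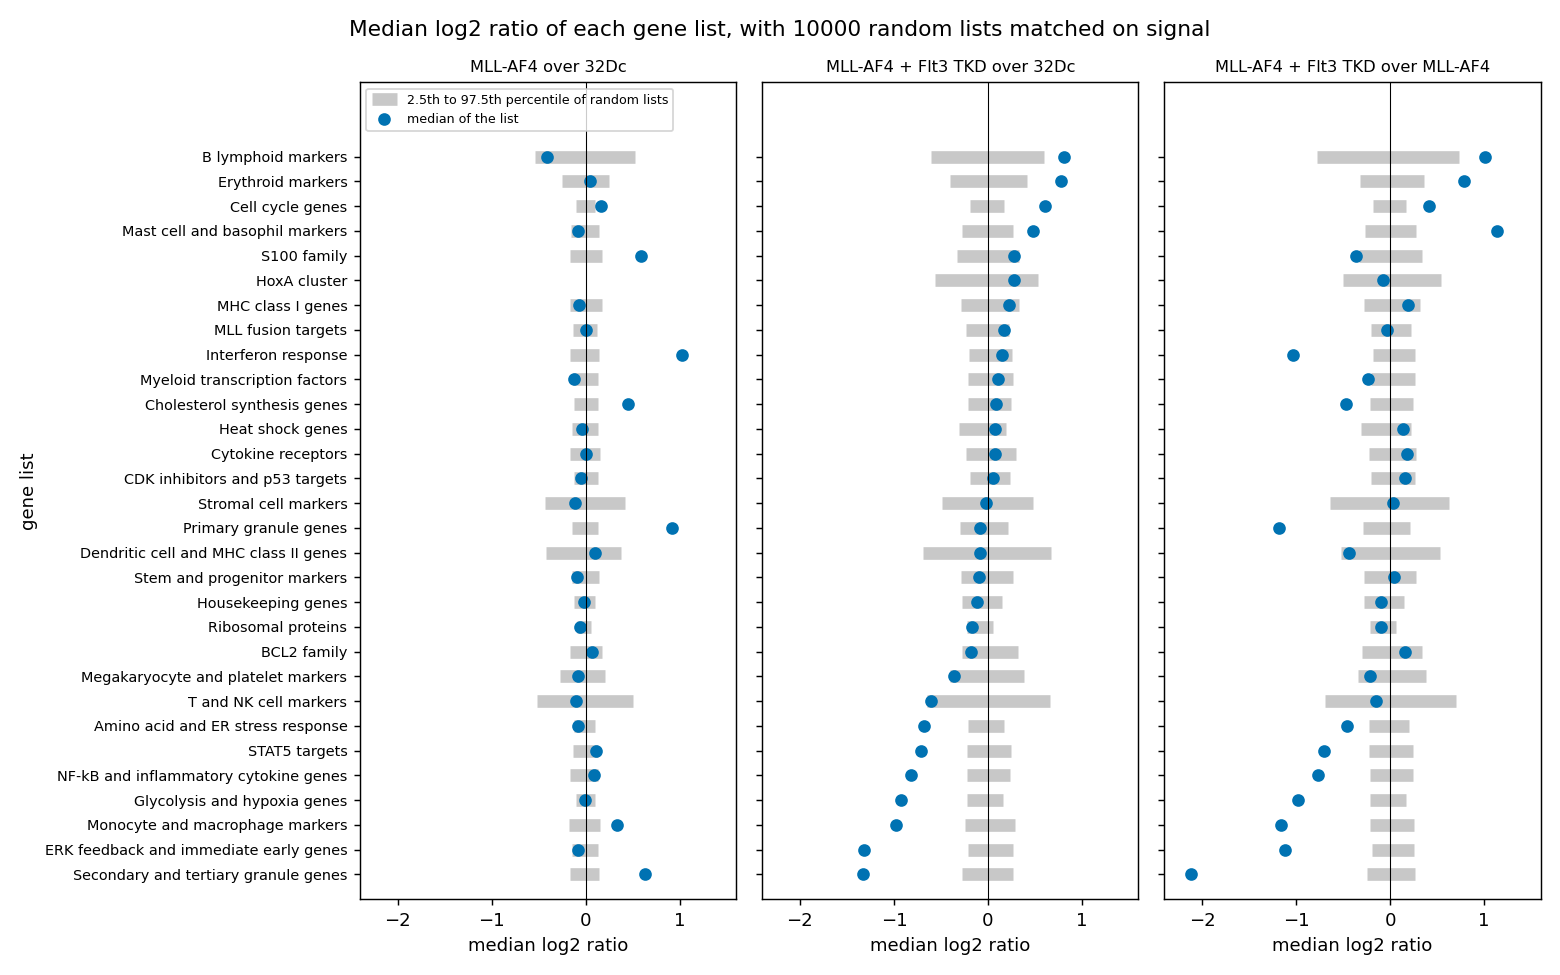
Median log2 ratio of each gene list (points) in the 3 comparisons, with grey bars for the range of 10000 random lists matched on signal. The interferon-response list stands at 1.03 for MLL-AF4 over 32Dc, and the secondary and tertiary granule list at −1.32 and −2.11 in the comparisons of MLL-AF4 plus Flt3 TKD.

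The third comparison sets cells with both proteins against those with MLL-AF4 alone. It reuses the arrays of the other comparisons, so its ratios follow from theirs and are not a separate observation. A gene high on the MLL-AF4 array alone is higher in the first comparison and lower here. Of the 150 genes at least 2-fold higher with MLL-AF4 than in 32Dc, 98 were at least 2-fold lower here. In 100 simulations of unchanged arrays, with the spread between MLL-AF4 and 32Dc as noise, a mean of 61.2 genes did so. Noise on the shared array may therefore account for much of this count. Granule, interferon-response and monocyte genes were lower as lists with both proteins than with MLL-AF4 alone, and 8 of 15 mast cell and basophil markers were higher. Elane gave 3206 with MLL-AF4 and 114 with both, 28.2-fold lower, S100a9 was 477-fold lower, from the highest signal of the MLL-AF4 array, where a saturated signal would make this fold too small, and S100a8 at least 668-fold lower. Gzmb was 36.6-fold higher (137 and 5014). Fcer1a, under the floor with MLL-AF4 alone, gave 8916 with both, at least 118-fold higher. S100a6 gave 1120 and 1731, a log2 ratio of 0.63.

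Of 10670 genes with a ratio, 384 were at least 2-fold higher and 561 at least 2-fold lower, of which 82 and 125 were bounds, and 628 and 436 when scaled to the hybridization controls. Other large ratios were those of Fgf3 (17.9-fold higher), Selp (15.2-fold), Klf1 (11.3-fold), Tgfbr3 (8.69-fold), Padi2 (8.43-fold), Aox4 (7.75-fold) and Gp5 (5.97-fold), and, as bounds, Rhag (at least 31.9-fold), Gtsf1 (at least 27.8-fold) and Oosp1 (at least 20.9-fold). Ifitm6 was 158-fold lower, Ngp 58.9-fold, Il6 40.5-fold, Phlda1 35.8-fold, Cd177 24.9-fold and Ccl3 24.6-fold. Stfa2l1 was at least 135-fold lower, Ltf at least 97.1-fold and Il2ra at least 74.5-fold. Another probe set went the same way for 154 of 159 higher and 227 of 238 lower genes, and reached 2-fold for 95 and 164.

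Secondary and tertiary granule genes had 12 of 18 members at least 2-fold lower and 0 higher (median −2.11, range −0.24 to 0.27, and −1.42 with the floor at the 75th percentile). The primary granule list, which holds more than granule proteins, had 6 of 12 lower and 1, Igsf6, higher (median −1.18, range −0.29 to 0.21). Mpo gave 14106 and 9807. Of 26 interferon-response genes 13 were lower and 0 higher (median −1.03, range −0.18 to 0.26), with Rsad2 at a bound of −3.69 and Usp18 at −2.75. Monocyte and macrophage markers had 11 of 18 lower and 0 higher (median −1.16, range −0.22 to 0.26). Lyz2 (−4.49) and Lyz1 (−3.91, on a less specific type of probe set) were among the lower members. STAT5 targets had 8 of 19 lower and 1, Bcl6, higher (median −0.71, range −0.22 to 0.24). ERK feedback and immediate early genes had 12 of 22 lower and 0 higher (median −1.12), glycolysis and hypoxia genes 10 of 21 and 0 (−0.98), NF-kB and inflammatory genes 8 of 21 and 0 (−0.76), and the amino acid and ER stress response 6 of 19 and 0 (−0.46), each below its range of random lists. Cholesterol synthesis genes had 2 of 17 lower, Pmvk (−1.247) and Mvd (−1.22), and a median of −0.47 (range −0.21 to 0.25).

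Mast cell and basophil markers had 8 of 15 members higher and 3 lower (median 1.14, range −0.26 to 0.28), with Mcpt8 at 2.49 and, as bounds, Hdc at 3.72 and Prg2 at 3.10. With the floor at the 25th percentile this median was 0.08. Erythroid markers had 3 of 8 higher and 0 lower (median 0.78, range −0.32 to 0.36), and cell cycle genes had 0 of 25 at 2-fold and a median of 0.42 (range −0.18 to 0.17). The receptor subunits Il3ra (log2 ratio 1.23) and Csf2rb2 (1.14) and the transcription factor Cebpa (1.23) were at least 2-fold higher with both proteins than with MLL-AF4 alone, and Csf2rb (0.61) was under 2-fold. MLL fusion targets had a median of −0.03 over 22 members. In the RefSeq order 3 runs of neighbours were lower than with MLL-AF4 alone. They were 30 genes from Lamtor2 to Pmvk (median −0.52, and −0.07 against 32Dc) and 100 genes from Sv2a to Dph5 (−0.50, and −0.16 against 32Dc). The other was a single window of 41 neighbours centred on Cycs (window median −0.49). Both long runs overlap runs that were raised with MLL-AF4 against 32Dc, where their medians were 0.41 and 0.30. They are thus in large part the same shifts of the MLL-AF4 array. B lymphoid markers had 2 of 4 measured members higher, Bank1 (2.27) and Cd79b (1.251). In all, 4 of 30 list medians lay above the range of random lists and 12 below it. The 12 include the S100 family (−0.36) and myeloid transcription factors (−0.24, with 6 members higher and 5 lower). The median of the transcription factors was 0.065 with the floor at the 75th percentile.

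**Figure D3:**
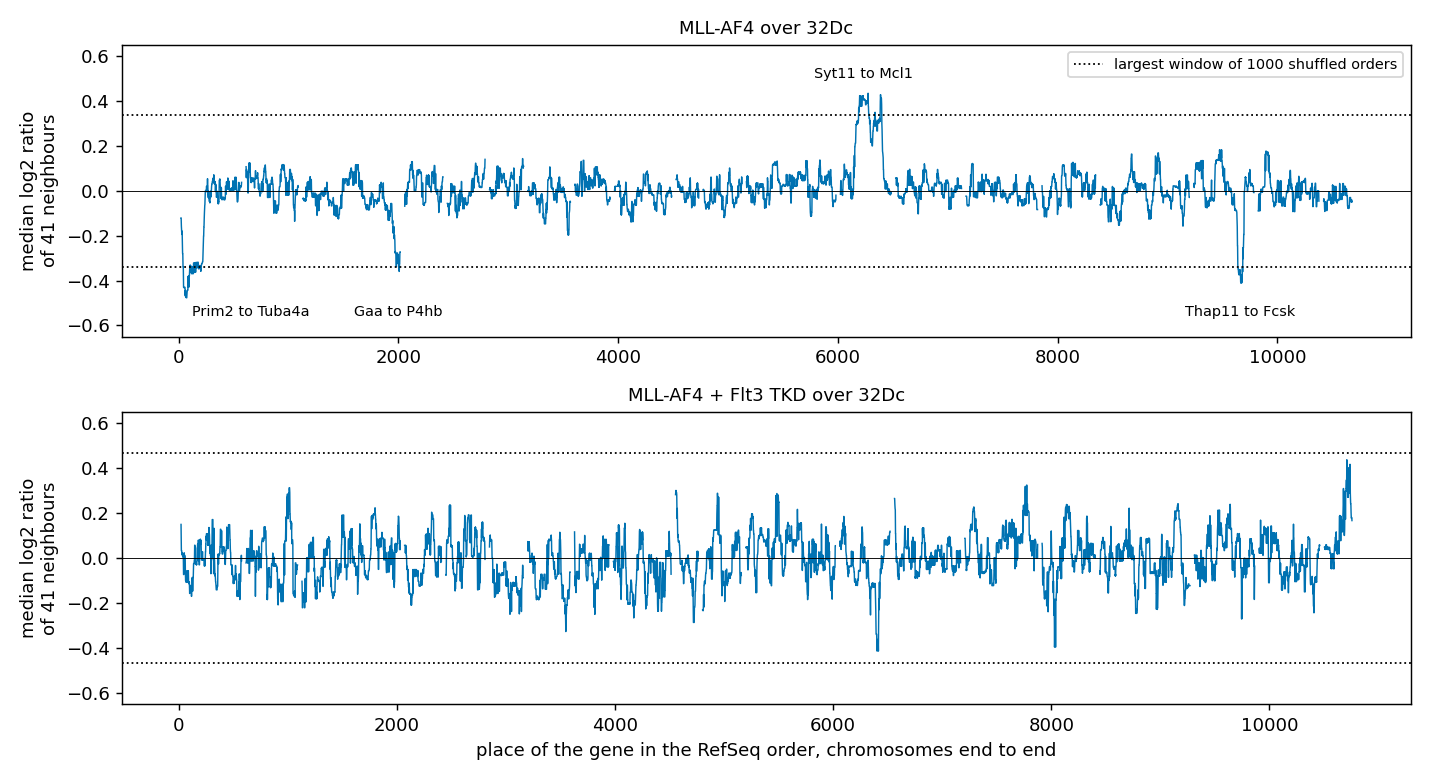
Running median of the log2 ratio over 41 neighbouring genes, in RefSeq order with chromosomes end to end and gaps at their ends, for MLL-AF4 over 32Dc (top) and MLL-AF4 plus Flt3 TKD over 32Dc (bottom). Dotted lines mark the largest window of 1000 shuffled orders, 0.34 and 0.47. In the top panel the stretch from Prim2 to Tuba4a has a median of −0.36 and that from Syt11 to Mcl1 one of 0.40. No window of the bottom panel passes its line, which lies further out. Its highest and lowest windows, 0.44 and −0.41, are of like size to the 0.43 and −0.48 of the top panel.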

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

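Probe sets without a single gene name, which the comparisons of genes do not use, also differed from the 32Dc array. Of these, 28 were at least 2-fold higher with MLL-AF4 and 148 with MLL-AF4 plus Flt3 TKD, and 51 and 152 were at least 2-fold lower. They were singled out because they hold signal outside the named genes. No explanation was tested for them.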

How the results depend on the processing

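Scaling to the hybridization controls was chosen after the data were seen, and the other settings were planned. The deposited scale, quantile normalization and the common median each kept all 6 counts of genes within 1.5 times the main count, as did both other choices of probe set. The deposited scale could not change the counts, since the arrays already shared 1 scale, and its values enter the tallies below as unmoved. With the floor at the 25th percentile the counts higher and lower were 893 and 1023 for MLL-AF4 against 32Dc, 1096 and 1532 for MLL-AF4 plus Flt3 TKD against 32Dc, and 1174 and 1434 against MLL-AF4. With the floor at the 75th percentile they were 43 and 18, 139 and 253, and 143 and 262, and at 3-fold they were 45 and 21, 86 and 208, and 101 and 248. A lower floor lets in dim genes and a higher one shrinks their ratios by construction. Scaled to the hybridization controls the counts were 780 and 347 against 32Dc and 628 higher against MLL-AF4, since this lifts the whole array of MLL-AF4 plus Flt3 TKD.

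Of 697 list medians under alternatives, 688 moved by at most 1.5-fold, without a change of sign from a main median outside the range of random lists. In all, 62 had another sign than the main median, of which 2 belonged to a main median outside that range and 60 to one within it. By a stricter criterion that was tried first, which set each shift against the width of the range of random lists, 47 moved. For MLL-AF4 plus Flt3 TKD against 32Dc, the floor at the 25th percentile put B lymphoid markers at −0.14, the opposite sign of the main 0.81, T and NK cell markers at 0.073 and the S100 family at −0.37. The 75th percentile put the S100 family at −0.31 and ERK feedback genes at −0.57. Against MLL-AF4, the lower floor put mast cell markers at 0.084 and B lymphoid markers at 0.23. The higher floor put secondary granule genes at −1.42 and myeloid transcription factors at 0.065, the opposite sign of −0.24. The cause was not tested beyond the change of members.

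Of the 208 named ratios of at least 2-fold, 1619 values under alternatives included 1558 still at 2-fold the same way, 61 under 2-fold and 0 of the opposite sign. Some ratios fell under 2-fold through the choice of probe set, as for Cdkn1b and Mapk8ip2. Genes within a few floors of background can carry bounds or ratios that the floor sets. The 61 values were not assigned to causes.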

Other observations

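All tests in this part were chosen after the patterns had been seen. Only for quantile normalization were the bounds of a test written before its values were known. For every other test the values, or others that give them away, had been seen when the bounds were written, so these tests are weak.

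A small set of genes was bright on a pair of arrays, at 8 times the floor or more, and under the floor on the other. These genes were picked by that pattern after the values were seen. With MLL-AF4 there were 4, Fcer1a, Gtsf1, Btg1 and Oosp1. They had signals of 6390, 3300, 2721 and 1023 in 32Dc and of 8916, 2102, 1329 and 1581 with MLL-AF4 plus Flt3 TKD. For Btg1 a dimmer probe set broke the pattern, with 685 in 32Dc, 11.1 with MLL-AF4 and 58.9 with both. With MLL-AF4 plus Flt3 TKD there were 16, including the granule regulator Gfi1 (1196, 2342 and 60.5 in the order 32Dc, MLL-AF4 and both), the osteoclast factor Tnfsf11 (1117, 1855 and 5.56), the costimulatory receptor Tnfrsf9 (815, 918 and 27.1), Ccn3 (2469, 2493 and 3.34), Cd200r3, Ctla2a, Dusp5, Il2ra and Cxcl2. The reverse, bright on 1 array and under the floor on both others, held for Prss28 and Rhag with MLL-AF4 plus Flt3 TKD, and for 0 genes on the other arrays.

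Neighbouring genes were shifted together on the MLL-AF4 array, in 6 runs of the gene order that exceeded all 1000 shuffles, 3 higher and 3 lower than in 32Dc. The longest were the 94 genes from Syt11 to Mcl1, with a median log2 ratio of 0.40, and the 163 genes from Prim2 to Tuba4a, with −0.36, and both were near 0 with MLL-AF4 plus Flt3 TKD against 32Dc (−0.02 and −0.07). Scaling or signal-dependent bias was argued against by quantile normalization, which left 0.39 and −0.35. A gain or loss of a chromosome segment in this culture is a candidate explanation: it needs a shift of the run as a whole, and the interquartile range was 1.11 and 0.924 times that of matched genes elsewhere. No DNA was measured and regulation of a whole domain stays open, while the values near 0 in the other culture with MLL-AF4 speak against MLL-AF4 alone as the cause. Shifts of neighbours may not be particular to the MLL-AF4 array. Windows with MLL-AF4 plus Flt3 TKD against 32Dc reached 0.44 and −0.41, but the shuffles of that pair reached 0.47, so no run was called.

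The S100 family, higher as a list on the MLL-AF4 array, lies inside the raised run from Syt11 to Mcl1. If its place in the run were the whole reason, its 8 members would stand no further from the run than random lists do. Their median lay 0.20 above that of the run, just past the upper end of the range of random lists (−0.15 to 0.18). These lists were drawn from genes outside the runs, and the interquartile range of the run was 1.11 times that of matched genes. So small an excess cannot tell whether the place in the run accounts for all of the list's shift or for a part of it. S100a6 was also higher with MLL-AF4 plus Flt3 TKD (log2 ratio 1.80 against 32Dc), where the run itself was not raised, with a median of −0.019, so the run cannot account for that difference.

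With MLL-AF4 plus Flt3 TKD, the lists of secondary and tertiary granule genes and of genes that respond to cytokines were lower than in 32Dc. Lower RNA quality was argued against by the 3' to 5' ratio of the Gapdh control, 0.953 times that of 32Dc, and scaling by the median of the secondary granule list, −1.05 when scaled to the hybridization controls. Lymphoid or stromal cells would dilute all myeloid transcripts alike, which the primary granule list argued against only weakly as the cause. Of its members 83.3% (10 of 12) lay above the median of the secondary granule list, Hp (−1.26 against −1.32) only just. The secondary list was picked because it was low, so a high share above its median was likely beforehand. The median of the primary granule list was −0.08, with 3 of 12 members at least 2-fold lower and 3 higher. Of 52 markers of such cells 38 were under the floor on both arrays and 2 were at least 2-fold higher, so a small share stays open. A weaker cytokine signal, a difference in medium (not given in the sources used here), the introduced proteins and the choice of cells in selection stay open too, and no biological explanation was tested.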
